A study of Vibrio cholerae with 4 samples.

How the data were processed

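Sequencing of RNA depleted of ribosomal RNA was applied to biofilms of wild-type Vibrio cholerae C6706, a strain of the cholera bacterium, grown in microfluidic chambers under flow. Per the labels' protocols, the biofilms were fed M9 minimal medium with 0.5% glucose at 25 °C, and starved biofilms were collected 1 h after glucose was taken out of the inflowing medium. RNA was isolated with Tri-reagent, treated with DNase, depleted of ribosomal RNA with a Ribo-Zero kit and made into strand-marking libraries with a NEBNext Ultra II Directional kit, per the labels' protocols. The series states 2 independent biological replicates per condition, each combined from technical replicates because of low sample volume. The pooling averages technical variation within a library, so the spread between the 2 libraries of a group measures the biological replicates and what remains of the technical variation.

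The authors deposited 2 tables of whole-number read counts per gene, with 2690 rows for chromosome 1 and 1003 rows for chromosome 2. Per the file headers, the columns used here hold total counts per gene, and gene positions refer to the RefSeq chromosomes of strain N16961, the reference strain. The submitters' processing notes name edgeR. The aligner, the read filters, the treatment of reads that map to several places and whether strand was used in counting are not given in the sources used here. A gene that overlaps another or lies antisense to it is therefore uncertain, and so is a gene with a near-identical copy. The 2 tables also hold 24 columns of scaled values, which were not used here.

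Each library was assigned to its group and replicate number from its title and treatment label. The 123 rows of ribosomal and transfer RNA were left out of library sizes and tests, except in the alternative that kept them. The reason is that depletion makes their share depend on the preparation. In the main test 3570 rows stayed. Counts of both chromosomes were analysed together. Library sizes were scaled by the trimmed mean of M values (TMM), which assumes that most genes do not change, and genes with too few counts were removed by filterByExpr, which left 3514. Normalised read counts are given in CPM, relative to the scaled library size. The main test was the quasi-likelihood test of edgeR 4.0.16 (robust dispersion, no covariates) in R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. All adjusted p-values of single genes are from this test unless another tool is named.

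A total of 23 gene lists was fixed before the data were examined, covering the biofilm matrix and its regulators, motility, growth, central carbon metabolism, starvation, secretion, iron, pili, chitin, phosphate and the superintegron. They were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated per list and with fry. Members with another annotated function were taken out before fold changes were seen. The genes named singly were set by a rule written before the data were examined. It took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 20 CPM and no overlap between groups, 17 biofilm, motility and carbon genes whatever their values, and up to 4 members of each list with the smallest adjusted p. Any other gene named was chosen after its values were seen, which is stated there.

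The tables name 495 rows by symbol and 3061 by locus tag. The name table used here is of the RefSeq annotation of assembly ASM23778v2, which carries other locus tags, so rows were matched by runs of at least 3 neighbouring genes with identical lengths, and then between matched neighbours at most 5 rows apart whose lengths differed by at most 15%. This matched 2327 rows. Of 345 matched rows with a symbol in both sources, 321 had the same symbol (93.0%). The match gave a symbol to 753 rows, and 74 further members of the lists were named from the published nomenclature of N16961. Other rows keep their locus tag and no function is given for them.

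Total counts per library ranged from 4310312 to 5733570. Confidence intervals of shares are 95% exact binomial intervals. They cover counting error only, since reads without molecular identifiers are not independent molecules and genes are not independent replicates. The counts of replicates were compared by chi-square, which gave 92.6 per degree of freedom in the control pair and 74.0 in the starved pair, so no library was a copy of another. The steps were tested on simulated data with the real means and library sizes, over 3514 genes in 5 runs. edgeR called 8.84% of genes simulated at 1.5-fold, 38.4% at 2-fold, 94.4% at 4-fold and 98.4% at 8-fold, and 9.13% of its calls were false, against 22.3% for DESeq2. A simulated list whose genes all rose had an unadjusted camera p under 0.05 in 5 of 5 runs at both correlation settings. One that did not move had so in 0 of 5. The real lists had to pass after adjustment over 23 lists, which was not simulated. The simulated genes varied independently of each other, while the estimated correlation within the real lists reached 0.99 (ATP synthase). The simulation therefore cannot tell which correlation setting is right for the real lists.

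Alternatives were other scalings (relative log expression, upper quartile, total count), no filter or a filter of 1 CPM in 2 libraries, ribosomal and transfer RNA kept, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood test, glmTreat against a fold change of 2, the replicate number as a block, each chromosome on its own, and each library left out in turn. With 2 libraries per group an exact permutation test of a single value cannot go below p = 0.333. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.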

Results

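The transcriptomes of Vibrio cholerae biofilms were compared before and after glucose was withdrawn from the flowing medium, the treatment the labels give as the trigger of dispersal. There were 2 control libraries and 2 libraries from biofilms starved for 1 h. Control replicates 1 and 2 held 5733570 and 5729117 counts, and starved replicates 1 and 2 held 4310312 and 5419761. Ribosomal and transfer RNA rows took 0.247% ± 0.0219 of all counts in the control libraries and 0.547% ± 0.0528 in the starved libraries (mean ± SD, n = 2 each). Log2 CPM correlated across genes at 0.966 within the control pair and at 0.975 within the starved pair, where genes are not independent replicates. Control replicate 1 correlated with the starved mean at 0.893 and control replicate 2 at 0.807.

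The comparison asks which genes change when a biofilm loses its carbon source. After 1 h without glucose, 24 of 34 genes for the use of other carbon sources, 38 of 52 flagellar genes, 9 of 9 genes of chemotaxis cluster II and 9 of 15 starvation genes were higher. Lower were 53 of 56 ribosomal protein, 8 of 8 ATP synthase, 15 of 18 nucleotide synthesis, 13 of 31 amino acid synthesis and 17 of 30 type VI secretion genes. As lists these 9 passed with camera, but each call was lost with an estimated correlation (adjusted p = 0.695 for each). This setting rests on the spread within 2 libraries per group, and 0 of the 23 lists passed with it. The starvation list lost its call although its estimated correlation, 0.02, was close to the preset 0.01. Its unadjusted camera p was 0.0039 with the preset and 0.113 with the estimate. A call lost this way therefore does not show that correlation between genes had produced it. The matrix protein genes rbmC and bap1 were lower too. Of 3514 genes tested, 1661 passed the threshold (47.3%), 908 higher and 753 lower, and 613 of the higher and 334 of the lower genes changed at least 2-fold. In 80.1% of genes the 2 groups did not overlap, where chance gives 33.3% on average. Genes vary together, so a single split of the libraries can separate many of them at once. The contrast is therefore a description and not a test. Under upper quartile scaling, which moved the median log2 fold change of all genes by -0.249, the split was 708 higher to 1148 lower (38.1% higher, against 54.7%).

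Glycerol genes were among the largest rises. The normalised read count of glpK (VCA0744, glycerol kinase; chromosome 2, 688094 to 689611) was 69.4 ± 10.4 CPM in the control and 4668 ± 489 CPM in the starved libraries (mean ± SD, n = 2), a log2 fold change of 6.07 ± 0.34 (SE; adjusted p = 0.00170). Its neighbour VCA0745 (689741 to 690596) rose from 20.7 ± 0.231 to 2292 ± 245 CPM, 111-fold (log2 6.79 ± 0.30; adjusted p = 0.00145). The genes glpD (VCA0657, glycerol-3-phosphate dehydrogenase) and glpT (VCA0137, glycerol-3-phosphate transporter) rose 58.9-fold and 34.2-fold, with adjusted p = 0.00201 and 0.00145. The other 4 of the 8 largest rises had no assigned function here: VC1273 (88.7-fold), VC0426 (39.4-fold), VC2704 (28.0-fold) and VCA0221 (26.5-fold). Without either control library the call of VC0426 was lost (adjusted p = 0.128 without replicate 1 and 0.140 without replicate 2).

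The gene gltB (VC2373, large subunit of glutamate synthase; chromosome 1, 2531065 to 2535657) was among the 8 largest falls, with a log2 fold change of -2.95 ± 0.45, from 4323 ± 1997 to 558 ± 171 CPM (adjusted p = 0.00726), and the adjacent gltD_1 fell by 2.67 ± 0.37 (adjusted p = 0.00628). The purine synthesis genes purH (VC0276) and purN fell, with log2 fold changes of -2.83 ± 0.40 and -2.58 ± 0.34. VC0275, next to purH, fell by 3.05 ± 0.35. The gene ilvC (VC0162), an enzyme of branched-chain amino acid synthesis, fell by 2.55 ± 0.36, and cspE (VCA0933), of the cold shock protein family, fell by 2.96 ± 0.32. Also among the 8 was bap1, described with the matrix proteins.

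**Figure D1:**
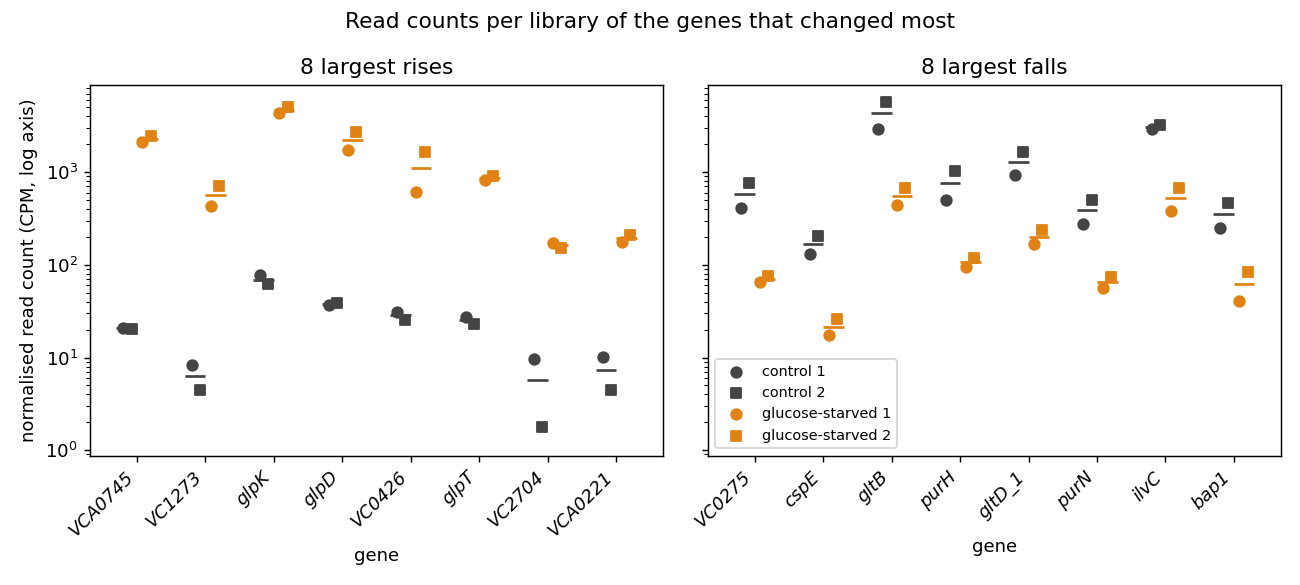
Normalised read counts (CPM, log axis) of the 8 called genes with the largest rise and the 8 with the largest fall, one symbol per library, with the mean of each group (n = 2) as a line; control is grey and glucose-starved is orange. In each gene the groups do not overlap, which the choice of genes required. The gene glpK lies at 69.4 CPM in the control mean and at 4668 CPM in the starved mean.

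Within the biofilm matrix, 2 of 6 tested matrix protein genes fell (2 adjusted over the list alone) and 0 rose. The gene rbmC (VC0930; chromosome 1, 993628 to 996501), which encodes a protein that anchors the biofilm to surfaces, fell from 474 ± 196 to 103 ± 27.2 CPM (log2 -2.20 ± 0.37; adjusted p = 0.00924). The gene bap1 (VC1888; chromosome 1, 2035185 to 2037260), for a related adhesin, fell from 357 ± 148 to 62.1 ± 30.3 CPM (log2 -2.52 ± 0.48; adjusted p = 0.0151), a call lost without control replicate 2 (adjusted p = 0.102). The gene rbmA (VC0928), for a protein that links neighbouring cells, had 377 and 961 CPM in the control libraries and 24.6 and 145 CPM in the starved ones, and its log2 fold change of -2.98 ± 1.17 did not pass (adjusted p = 0.130) but did with DESeq2 (adjusted p = 0.0284). The gene rbmB (VC0929) had a log2 fold change of 0.12 ± 0.14 (adjusted p = 0.534), which turned to -0.13 under upper quartile scaling. The gene rbmE (VC0932) had one of -1.02 ± 0.68 (adjusted p = 0.285), which was 0.03 without control replicate 2. As a list the matrix proteins did not pass (median log2 fold change -1.61; camera adjusted p = 0.0568, and adjusted p = 0.695 with an estimated correlation). Without control replicate 1 the list passed (camera adjusted p = 0.0110) and 4 of its genes were lower, and it also passed without starved replicate 2 (camera adjusted p = 0.0173). Without control replicate 2 its median was -0.82 with 1 gene lower, and without starved replicate 1 it was -1.29 with 0 lower.

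Of the 18 genes for synthesis and export of Vibrio polysaccharide, the main sugar polymer of the matrix, 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median log2 fold change of -0.71 (camera adjusted p = 0.136, and adjusted p = 0.861 with an estimated correlation). The gene that rose was vpsN (VC0936; log2 1.26 ± 0.19; adjusted p = 0.00723). The genes vpsA and vpsL did not pass, and their control libraries differed widely. The gene vpsA (VC0917) had 62.0 and 239 CPM in the control and 12.4 and 40.2 CPM in the starved libraries (log2 -2.51 ± 1.04; adjusted p = 0.145). The gene vpsL (VC0934) had 23.8 and 111 against 13.3 and 34.9 CPM (log2 -1.47 ± 1.02; adjusted p = 0.318). The values of vpsU (VC0916) and vpsD (VC0920) were -2.78 ± 0.90 and -1.03 ± 0.42 (adjusted p = 0.0875 and 0.108), and both passed as lower with DESeq2 (adjusted p = 0.000068 and 0.0415). Without control replicate 1 the list passed (camera adjusted p = 0.00133), with 9 genes lower, and without control replicate 2 it had 3 genes higher, 0 lower, a median of -0.03 and a vpsL value of 0.05. Under upper quartile scaling and with DESeq2 it had 2 genes lower. It also passed without starved replicate 2 (camera adjusted p = 0.0198).

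**Figure D2:**
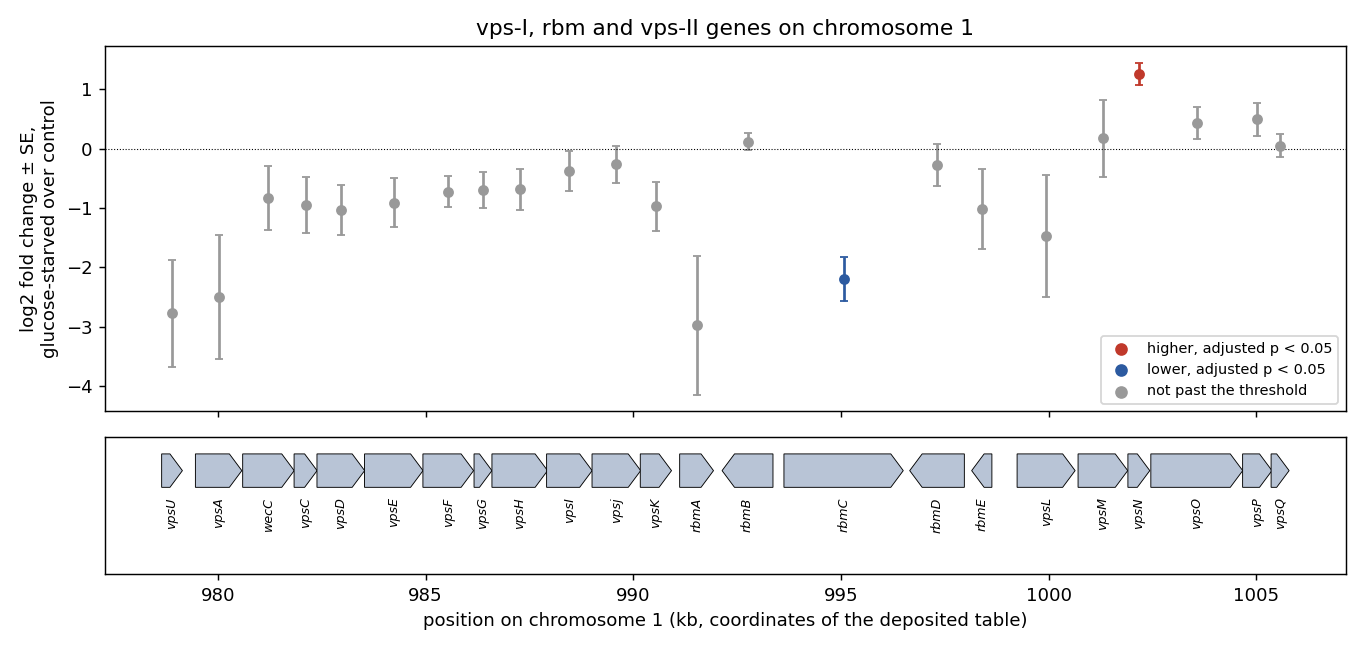
Log2 fold change (glucose-starved over control, points; bars are ± SE from edgeR's fit, n = 2 per group) of the 23 genes from vpsU to vpsQ, drawn at their positions on chromosome 1 in kb, with the genes as arrows in their direction below. Only rbmC (blue) is called lower and only vpsN (red) higher, and 17 of the 23 values lie below 0, many with wide errors.

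Among 16 biofilm and dispersal regulators, a list fixed to go either way, 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.250, and adjusted p = 0.695 with an estimated correlation). Both that fell belong to one polyamine-sensing pathway. The gene nspS (VC0704), for its periplasmic sensor, fell by 1.97 ± 0.22 (adjusted p = 0.00533). The gene mbaA (VC0703), for its membrane partner that acts on the second messenger cyclic di-GMP, fell by 1.67 ± 0.19 (adjusted p = 0.00533). The gene vpvC (VC2454), for a diguanylate cyclase, rose by 1.66 ± 0.21 (adjusted p = 0.00595). The gene lapG (VCA1081), for a protease that releases cells from their surface adhesins, rose from 49.3 ± 0.932 to 114 ± 9.08 CPM (log2 1.20 ± 0.15; adjusted p = 0.00595). The gene lapD (VCA1082), for the cyclic di-GMP receptor that restrains it, rose from 337 ± 6.20 to 658 ± 60.4 CPM (log2 0.97 ± 0.20; adjusted p = 0.0135). The call of lapD was lost when each chromosome was analysed on its own (adjusted p = 0.0843). The matrix activator vpsR (VC0665) rose by 0.88 ± 0.24 (adjusted p = 0.0309), a call lost under upper quartile scaling (adjusted p = 0.0876). The other activator, vpsT (VCA0952), had a value of 0.02 ± 0.21 (adjusted p = 0.927), and -0.23 under upper quartile and -0.01 under total count scaling. The quorum-sensing regulator hapR (VC0583) had 1452 and 761 CPM in the control and 3190 and 1370 CPM in the starved libraries (log2 1.04 ± 0.53; adjusted p = 0.159).

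Motility genes rose broadly. Of 52 flagellar and motor genes 38 rose and 0 fell (43 and 0 adjusted over the list alone), and all 9 genes of chemotaxis cluster II rose (9 adjusted over the list alone), with camera adjusted p = 4.85e-05 and 0.00768. With an estimated correlation both calls were lost (adjusted p = 0.695 for each). The gene flgM (VC2204), for the anti-sigma factor of late flagellar genes, rose from 123 ± 10.8 to 429 ± 12.9 CPM (log2 1.80 ± 0.18; adjusted p = 0.00533), and motX (VC2601), for a part of the motor, rose by 1.61 ± 0.22 (adjusted p = 0.00622). In the chemotaxis list cheV (VC2202) rose 3.99-fold and cheY (VC2065), for the response regulator that acts on the motor, 2.55-fold (adjusted p = 0.00865 and 0.00765). The core flagellin gene flaA (VC2188) had a value of 0.82 ± 0.28 (adjusted p = 0.0569). It passed with DESeq2 (adjusted p = 0.0138), with each chromosome on its own (0.0308) and without control replicate 1 (0.0432) or 2 (0.0356). Of 17 genes of the MSHA pilus, a type IV pilus used in surface attachment, 10 rose and 0 fell (10 adjusted over the list alone; camera adjusted p = 0.0377, and adjusted p = 0.695 with an estimated correlation), and VC0413 rose 2.74-fold. Under upper quartile scaling 24 flagellar and 4 MSHA genes were higher, and the MSHA list test was lost (adjusted p = 0.0647), as it was without control replicate 1 (adjusted p = 0.0847) and without starved replicate 2 (adjusted p = 0.127).

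Of 56 ribosomal protein genes 53 fell and 0 rose (54 and 0 adjusted over the list alone), with a median log2 fold change of -1.66. The gene rplT (VCA0290) went from 2298 ± 336 to 576 ± 69.7 CPM (adjusted p = 0.00622). All 8 ATP synthase genes fell (8 adjusted over the list alone), and atpD (VC2764), for the beta subunit, fell by 1.56 ± 0.28. Of 18 purine and pyrimidine synthesis genes 15 fell (17 adjusted over the list alone), among them purM (VC2226), which was 5.15-fold lower. Of 31 amino acid synthesis genes 13 fell (12 adjusted over the list alone), among them the histidine genes hisF and hisB, which were 2.34-fold and 2.29-fold lower. Of 11 heat shock and chaperone genes 5 fell (5 adjusted over the list alone), including dnaJ (VC0856) and htpG (VC0985), 2.25-fold and 1.98-fold lower. The camera adjusted p was 2e-16 for ribosomal proteins, 0.000510 for ATP synthase, 5.83e-06 for nucleotides, 0.000246 for amino acids and 0.0377 for heat shock. With an estimated correlation each of the 5 calls was lost (adjusted p = 0.695). Without control replicate 1, 22 amino acid and 8 heat shock genes were lower. The heat shock list was lost without control replicate 2 (camera adjusted p = 0.0932), without starved replicate 1 (adjusted p = 0.0589) and under upper quartile scaling (adjusted p = 0.0553, with 9 genes lower).

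Genes for the uptake and catabolism of carbon sources other than glucose rose in 24 of 34 cases and fell in 0 (24 and 0 adjusted over the list alone; camera adjusted p = 3.36e-12, and adjusted p = 0.695 with an estimated correlation). Besides the glycerol genes above, glpQ (VCA0136), for glycerophosphodiester phosphodiesterase, rose from 33.9 ± 1.30 to 383 ± 2.21 CPM (adjusted p = 0.00151). Of 6 fatty acid degradation genes 4 rose (5 adjusted over the list alone; camera adjusted p = 0.0257, and adjusted p = 0.695 with an estimated correlation), with fadB (VC2758) 6.19-fold and fadA (VC2759) 5.28-fold higher. This list was lost without starved replicate 1 (adjusted p = 0.0528). In glycolysis and glucose uptake 1 of 14 genes rose and 1 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.377, and adjusted p = 0.865 with an estimated correlation). A pyruvate kinase gene, pyk (VC2008), rose 6.56-fold, while the paralogous pykF (VC0485) had a value of -0.67 ± 0.22 that did not pass (adjusted p = 0.0519) but did under each other scaling, with limma-voom and with DESeq2 (adjusted p = 0.00285 to 0.0464). The gene tpiA (VC2670), for triose phosphate isomerase, fell by 0.89 ± 0.26, and the glucose transporter gene ptsG (VC2013) had 4297 ± 432 CPM in the control and 5455 ± 846 CPM in the starved libraries (adjusted p = 0.368). In this list 5 genes were lower without control replicate 1, under upper quartile scaling and with DESeq2. Without control replicate 2 there were 3, and under relative log expression and total count scaling and with limma-voom 2.

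In the gluconeogenesis and acetate list 1 of 5 genes rose and 1 fell (1 and 1 adjusted over the list alone; median -0.06 but mean 0.47; camera direction up, adjusted p = 0.964). Without control replicate 1 there were 0 higher and 2 lower, without control replicate 2 there were 0 and 1, and with DESeq2 and each chromosome on its own 2 and 1. The acetyl-CoA synthetase gene acs (VC0298) rose 7.67-fold, from 345 and 123 CPM to 2398 and 1191 CPM (adjusted p = 0.0204), a call lost without either control library (adjusted p = 0.0517 without replicate 1 and 0.103 without replicate 2). The gene ppsA (VCA0987), for phosphoenolpyruvate synthase, fell by 0.87 ± 0.23, and pckA (VC2738) had a value of 0.77 ± 0.28 (adjusted p = 0.0632) but passed with DESeq2 (adjusted p = 0.0142) and with each chromosome on its own (0.0373). In the tricarboxylic acid cycle and glyoxylate shunt 1 of 16 genes rose, sdhC (VC2091; 1.77-fold), and 0 passed when adjusted over the list alone (camera adjusted p = 0.438). The shunt genes aceA and aceB, picked after their values were seen, had larger values but did not pass. For aceA the control libraries held 304 and 77.9 CPM and the starved ones 2220 and 558 CPM (log2 2.86 ± 1.11, adjusted p = 0.118). For aceB the log2 fold change was 2.84 ± 1.19 (adjusted p = 0.147). With the replicate number as a block 5 genes of the list were higher. The call of sdhC was lost under upper quartile scaling (adjusted p = 0.0532), with 0 genes higher, while DESeq2 had 4 higher, among them sdhB (adjusted p = 0.0242). There were 2 higher without control replicate 1 and with each chromosome on its own. Of 3 glycogen genes, glgC on chromosome 2 rose 6.83-fold, while the list's median was -0.48 and its mean 0.57 (1 higher and 1 lower adjusted over the list alone; camera direction up, adjusted p = 0.902), and 2 of them were lower under upper quartile scaling and with DESeq2.

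Of 15 starvation and stationary-phase genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.00896, and adjusted p = 0.695 with an estimated correlation). Without control replicate 1 there were 10 higher and 3 lower, with a median of 1.68 against 1.01, and under upper quartile scaling 8 higher and 1 lower. The gene rpoS (VC0534; chromosome 1, 564732 to 565739), for the stationary-phase sigma factor, rose from 1413 ± 362 to 4731 ± 9.89 CPM (log2 1.74 ± 0.31; adjusted p = 0.00924). The catalase genes katG (VC1560) and katB (VC1585) rose 12.7-fold and 4.68-fold, dps (VC0139), for a DNA-binding ferritin, rose 12.0-fold and hpf (VC2530), for a ribosome hibernation factor, 4.60-fold. The gene crp (VC2614), for the cyclic AMP receptor protein, had a value of -0.50 ± 0.23 (adjusted p = 0.129), and it passed as lower under upper quartile scaling (adjusted p = 0.0483) and without control replicate 1 (adjusted p = 0.0376).

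Type VI secretion genes, which encode a contractile apparatus that injects effectors into neighbouring cells, fell in 17 of 30 cases and rose in 0 (17 and 0 adjusted over the list alone; camera adjusted p = 1.59e-06, and adjusted p = 0.695 with an estimated correlation). The sheath gene tssC (VCA0108) went from 189 ± 19.7 to 54.1 ± 8.71 CPM. The hcp copies VC1415 and VCA0017 are uncertain, since their counts were identical in every library. Of 33 iron uptake genes 8 fell and 1 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.0377, and adjusted p = 0.695 with an estimated correlation), with vctG (VCA0229) and vctD (VCA0228), of a siderophore transporter, 3.85-fold and 2.87-fold lower. This list was lost without control replicate 1 (adjusted p = 0.202), without starved replicate 2 (adjusted p = 0.122) and under upper quartile scaling (adjusted p = 0.0576). Of 16 chitin genes 5 rose (5 adjusted over the list alone; camera adjusted p = 0.0802, and adjusted p = 0.695 with an estimated correlation), with the chitinase genes chiA2 (VCA0027) and chiA1 (VC1952) 11.7-fold and 3.36-fold higher. Of 10 phosphate starvation genes 3 rose (2 adjusted over the list alone; camera adjusted p = 0.278), led by VCA0070, which was 2.96-fold higher.

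**Figure D3:**
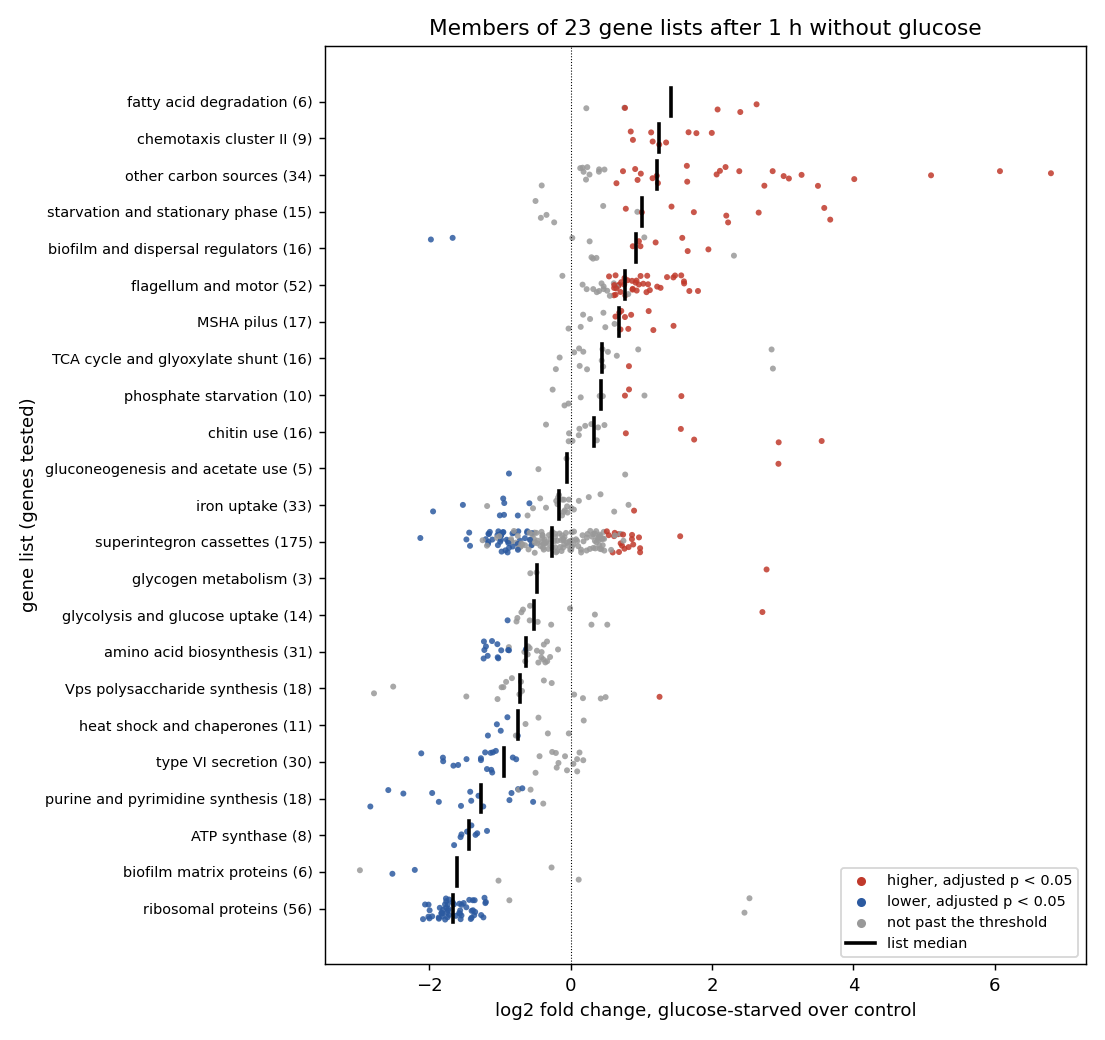
Log2 fold change (glucose-starved over control) of each tested member of 23 gene lists, one point per gene, coloured by whether it passed an adjusted p of 0.05, with the list median as a black bar and the number of genes tested in brackets. Ribosomal proteins lie at a median of -1.66, with 53 of 56 lower, and the other carbon sources at a median of 1.23, with 24 of 34 higher.

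The share of genes called was alike on chromosomes 1 and 2 (47.1% and 47.6%; Fisher's exact test across genes, two-sided, p = 0.821), and their directions differed. On chromosome 1, 22.9% of 2537 genes were higher and 24.2% lower, and on chromosome 2, 33.5% of 977 were higher and 14.1% lower (Fisher's exact test across genes, two-sided, p = 3.03e-10 for higher and 1.74e-11 for lower), where genes are not independent replicates. The median log2 fold change was -0.058 and 0.240. Chromosome 2 took 13.4% ± 2.50 of counts in the control and 22.0% ± 0.368 in the starved libraries (mean ± SD, n = 2), with 15.2% and 11.6% in control replicates 1 and 2. For this difference of 8.61 percentage points the two-sided exact permutation test gave p = 0.333, the smallest this design allows. The superintegron of chromosome 2, an array of gene cassettes mostly of unknown function, went the other way: of 175 genes 19 were higher and 41 lower (17 and 34 adjusted over the list alone; camera adjusted p = 0.00533, and adjusted p = 0.695 with an estimated correlation). It had 7 higher and 70 lower genes under upper quartile scaling and 5 higher and 74 lower with each chromosome analysed on its own. Without control replicate 2 it had 9 higher and 39 lower. Without control replicate 1 it had 29 higher and 33 lower, and its list test was lost (adjusted p = 0.0847).

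All calls were made with edgeR's quasi-likelihood test on 2 libraries per group, and 14 of the 23 lists passed with camera. With fry 0 lists passed, 11 did at an unadjusted p under 0.05, and 14 passed its test of change in either direction. The calls depend on both starved libraries: edgeR called 10 genes without starved replicate 1 (1288 at an unadjusted p under 0.05) and 0 without starved replicate 2 (1496 at an unadjusted p under 0.05), since the spread then comes from the control pair alone. This applies to every count of genes above, while 12 and 14 lists passed with camera without these libraries. The 14 were not the same lists as above: iron uptake and the MSHA pilus were lost, and Vps synthesis and the matrix proteins were gained.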

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

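The test of ribosomal RNA depletion was chosen only after the result was seen, and the test of short genes before. The rows of ribosomal and transfer RNA, which were left out of the main comparison, stood above the control level in both starved libraries. Ribosomal RNA took 0.387% of counts against 0.185% in the control, and transfer RNA 0.161% against 0.0616% (means, n = 2 each). Less complete depletion of ribosomal RNA is argued against as the sole source, because transfer RNA, which the depletion does not target, was 3.07 and 2.15 times its control mean in starved replicates 1 and 2. Better recovery of short RNA stays open. Ribosomal protein genes, which fell, were left out of this test. Among the other genes, the median log2 fold change of those under 300 bp lay 0.253 above that of longer ones (95% bootstrap interval over genes 0.112 to 0.402). This is the direction it predicts, although below the 0.5 set for it in advance. The length of a gene is not that of its transcript, so the test cannot settle the recovery of RNA as short as transfer RNA. A change of RNA composition in starved cells, in which stable RNA makes up more of the total as messenger RNA falls, may remain and was not tested.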

How the results depend on the processing

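No gene called in the comparison reversed sign under any alternative, and counts of genes lay within 1.5 times the reported ones under relative log expression, total count, the low-count filters, ribosomal and transfer RNA kept, DESeq2 (1685), limma-voom (1649), the legacy test and each chromosome on its own (1684). Exceptions were upper quartile scaling, with 1148 lower genes, and glmTreat, which asks for more than a 2-fold change and called 295 genes (254 higher, 41 lower; 7.50% of genes on chromosome 1 and 10.7% on chromosome 2). Leaving out 1 library gave 0 to 1856 genes, 0 to 944 higher, 0 to 912 lower, 0 to 53.2% called on chromosome 1 and 0 to 51.2% on chromosome 2. DESeq2 and limma-voom were not run on 3 libraries, and the lone library of a group is then assumed to vary like the other pair. Lists called numbered 0 with an estimated correlation and 0 with fry, against 14. Some values that were not called changed sign. With 1 library left out, vpsL ranged from -2.339 to 0.050, rbmE from -1.616 to 0.032 and vpsT from -0.179 to 0.301. The gluconeogenesis list turned direction without control replicate 1 and without starved replicate 1 (adjusted p from 0.823 to 0.954 over the 4 libraries left out). Under upper quartile scaling rbmB was -0.134 and vpsT -0.231, and vpsT was -0.012 under total count scaling, -0.001 with ribosomal and transfer RNA kept and -0.290 with each chromosome on its own. The cause was not tested in these cases. With the replicate number as a block, 1875 genes were called (1032 higher, 843 lower), 9 Vps and 4 matrix protein genes were lower and both lists passed (adjusted p = 0.00611 and 0.00206). Same-numbered libraries deviated together (correlation across genes 0.517), but 2 pairs without a label of a shared batch do not show pairing. In the simulation, with far fewer changed genes than were called here, 2-fold changes were recovered in 38.4% of cases. A gene that was not called may still have changed.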

Other observations

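The genes in this paragraph and the next were chosen after their values were seen. The 5 histidine utilisation genes hutH, hutU, hutG, hutI and hutC rose by 2.06 to 2.69 on the log2 scale, hutH from 58.5 and 60.2 CPM to 306 and 408 CPM (adjusted p = 0.00441). The propionate genes prpB, prpC and prpF rose by 2.61 to 3.06. The fumarate reductase genes frdA, frdC and frdD rose by 1.83 to 1.85, and napA and napF, of the periplasmic nitrate reductase, by 1.68 and 1.40. The chemoreceptor genes mlp37 (VCA0923) and mlp24 (VC2161) rose by 3.77 ± 0.48 and 2.30 ± 0.36 (adjusted p = 0.00603 and 0.00765). The toxin genes hlyA (VCA0219; haemolysin) and makA rose by 3.48 ± 0.46 and 2.11 ± 0.61 (adjusted p = 0.00644 and 0.0395), as did makB, makC, makD and makE, by 2.03 to 2.52. The genes rpoB and rpoC, for subunits of RNA polymerase, fell by 1.33 ± 0.32 and 1.22 ± 0.31.

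Genes of the toxin-coregulated pilus and its accessory colonisation factors went in both directions. Of 17 such genes 3 rose, the regulators tcpP (1.43 ± 0.20) and tcpH (0.91 ± 0.19) and the pilin gene tcpA (1.23 ± 0.23), and 3 fell, tcpJ, acfB and acfD, while 11 did not pass. The ribosomal protein paralogs rpmE2 and rpmJ_1 did not fall with their list: rpmE2 had 115 CPM in starved replicate 2 and 10.3, 11.6 and 11.7 CPM in the other 3 libraries, and rpmJ_1 had 93.5 CPM against 9.33, 9.45 and 9.59 CPM.

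Of the tests below, the 3 on replicates were chosen only after the result was seen, and the 3 on chromosome 2 before. Of 61 genes with a mean of at least 20 CPM that differed over 2-fold between replicates 1 and 2 in both groups, all 61 did so in the same direction, 57 higher in replicate 1 (for example hapA, for the haemagglutinin protease, picked after its values were seen, with 3354 and 126 CPM in the control and 14660 and 2593 CPM in the starved libraries) and 4 lower (vpsU, vpsA, rbmA and vpsL). Starved RNA mixed into control replicate 1 cannot be the source of the 57 genes as a set. The share of starved RNA they would need had a median of 31.2%. In control replicate 1, 26.2% of the 908 higher genes had less than that share of their lower starved level. Those of the 57 that need a smaller share are not covered by this. For the nearer position of control replicate 1 to the starved libraries the needed share was 12.8%, and a starved RNA admixture of that size stays open, since the result depends on the cut. Of the 133 higher genes whose control replicate 2 level lay below that share of their lower starved level, 17.3% lay below it in control replicate 1 too (95% exact binomial interval over genes 11.3 to 24.8) and 6.77% below 0.5 of it (3.14 to 12.5), against a bound of 5%. Their median implied share was 11.4%, although 8 glp genes had a median of 3.55% of their starved level there; a first form of the test, over all 908 higher genes, gave 3.19%, where most rose too little to lie below the share. A shared run or culture day of equal numbers cannot be told apart from chance or from a difference in culture state, with 1 contrast per group and a correlation across genes of 0.517. No biological explanation was tested.

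Chromosome 2 took a larger share of counts in starvation, by 8.61 percentage points. A few abundant genes are argued against, since without the 20 most counted genes of chromosome 2 the difference was 7.07 points, and without the ribosomal protein and ATP synthase lists it was 7.93 points. Genomic DNA is argued against as the sole source. The 68.6% of reads it would need would give every gene 194 CPM per kb in the starved libraries, and 66.4% of genes lay below that. A smaller share of DNA, giving part of the difference, was not tested. Gene dosage, with fewer replication forks per cell and hence fewer copies near the origin of chromosome 1, may contribute. The ribosomal protein and ATP synthase lists were left out of its test. Chromosome 1 genes nearer the terminus than the origin had a median log2 fold change 0.191 above the others (95% bootstrap interval over genes 0.110 to 0.281). The rule for the bound was set in advance. The bound itself, 0.149, was computed from the observed difference between the medians of the 2 chromosomes (0.298). The value of 0.191 lies above it, but the interval spans it, so gene dosage stays open. No biological explanation was tested.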
